A study of Homo sapiens with 18 samples.

How the data were processed

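Gene expression was measured by RNA sequencing in 18 scalp punch biopsies, 6 from controls, 6 from people with alopecia areata before tofacitinib and 6 from the same people after it. Per the labels, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The values the authors deposited are FPKM, as the first line of the table says. The submitters' notes list bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3, DESeq and the mouse build mm10 without saying what each did, although the gene symbols are human. The program that computed FPKM, the human build and the annotation are not given in the sources used here, so genes are named by the deposited symbols and no coordinates are given.

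The table held 25549 rows, of which 1 held no numbers. Y-linked genes, XIST and TSIX (120 in all) were left out of all tests and tables. Other X-linked genes stayed in. In all 25428 genes were kept, 2758 of them at 0 in all libraries. Of the symbols, 87.9% matched a reference annotation, 20028 as current and 2330 as older symbols, and 26 had been turned into dates. There were 0 pairs of libraries with identical values. FPKM give no read counts, so the absolute depth was unknown and no counting intervals were computed. The smallest step between low values is set by a library's depth, and the steps of 4222 genes with a median FPKM below 0.3 gave the depth of each library relative to the others.

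The comparisons, gene lists, tests, filters, rule for naming genes and other settings to be tried were set before the data were examined. Exceptions are given in the closing section. Genes at 1 FPKM or more in at least 6 libraries were tested (15903). Values were transformed to log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with all 18 libraries in a single fit, 15 residual degrees of freedom, and empirical Bayes moderation with trend and robust settings. The contrasts were before treatment minus control, after minus before treatment, and after treatment minus control. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The sample titles tie each after-treatment biopsy to the before-treatment biopsy of the same patient, so the after minus before contrast was also fitted on the 12 patient libraries with the patient as a fixed block, and with the patient as a random block over 18 libraries.

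The 37 gene lists were cytotoxic lymphocyte, T cell, regulatory T cell and checkpoint, interferon gamma response, type I interferon response, MHC class I and class II presentation, gamma-chain cytokine and JAK-STAT, NKG2D ligand, type 2 cytokine, B and plasma cell, macrophage and dendritic cell, mast cell, hair shaft keratin, hair keratin-associated protein, inner root sheath, hair matrix regulator, bulge and outer root sheath, dermal papilla, melanocyte, sebaceous gland, cholesterol synthesis, eccrine sweat gland, epidermal differentiation, epidermal activation, adipocyte, skeletal muscle, smooth muscle, endothelial, fibroblast and matrix, nerve and Schwann cell, proliferation, immediate early and heat shock, blood and haemoglobin, and the 3 lists of the alopecia areata disease activity index (ALADIN). The ALADIN lists share members with other lists. Each list was compared with all other tested genes by camera with a preset correlation of 0.01, and again with an estimated correlation. The rotation test fry asked whether the genes of a list moved, on balance, in a single direction. A list score per library was the mean log2(FPKM + 1) of the members minus the control mean. Scores used all members in the table, also those below the expression filter, which the list tests left out. Scores were compared by exact two-sided permutation tests over 924 splits (smallest p 0.00216) and, within patients, over 64 sign patterns (smallest p 0.03125), adjusted over the 37 lists. The sign-flip p is given unadjusted, and the smallest adjusted value was 0.136. Correlations across the 6 patients used all 720 pairings (smallest p 0.00278).

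Genes were named by 3 criteria in each comparison. The first was the 8 largest rises and 8 largest falls past an adjusted p of 0.05 with a mean in the higher group above 10.55 FPKM, the median over tested genes. Unnamed loci, variable segments of immune receptors, Y-linked genes, XIST and TSIX were left out. The second was up to 4 members of each list with the smallest p. The third was JAK1, JAK3 and the ALADIN members. Not every gene that meets these criteria is given.

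The alternatives were no filter (22670 genes), a filter of 5 FPKM (11535 genes), pseudocounts of 0.1 and 10, median-ratio rescaling, quantile normalization, limma without trend or robust settings, only the libraries of the groups compared, array weights, leaving out each library or each patient, leaving out the patient sampled at week 36, the patient blocks, the other list tests, and scores from medians or z-scores. The fits were tested on simulated data with changes added to 200 genes. Of genes changed by 1 on the log2 scale, limma recovered 91.0% in the first contrast, 88.1% in the after minus before contrast (79.1% with the patient block) and 88.1% in the third, and of those changed by 0.5 it recovered 61.2%, 46.3% (25.4% with the block) and 47.8%. In 1000 simulated sets without a difference the exact permutation test fell below 0.05 in 4.8% and the sign-flip test in 3.1%. Scores, permutation tests and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.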

Results

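RNA sequencing was performed on 18 scalp punch biopsies. Alopecia areata is an autoimmune form of hair loss in which lymphocytes surround the growing hair follicle. It affects patches of scalp, the whole scalp (totalis) or the whole body (universalis). A group of 6 biopsies came from control scalp, 6 came from people with alopecia areata before treatment, and 6 came from the same people during an open-label pilot trial of tofacitinib. Tofacitinib is an oral inhibitor of the Janus kinases JAK1 and JAK3, which carry signals from interferon gamma and from the gamma-chain cytokines. The biopsies after treatment were taken at week 24 in 5 patients and at week 36 in 1 patient, replicate 1. The deposited values were FPKM (fragment counts scaled for transcript length and library size), which do not give the number of reads, so the absolute depth was unknown. The spacing of low values gave the relative depth. Relative to the shallowest library it averaged 1.57 ± 0.18 in controls, 1.37 ± 0.23 before treatment and 1.40 ± 0.31 after treatment (SD, n = 6 each), and the deepest library was 1.91 times as deep as the shallowest. Genes at 1 FPKM or more numbered 15336 ± 173 in controls, 15531 ± 140 before and 15383 ± 86.6 after treatment. Within groups, Pearson's r between libraries across genes lay between 0.966 and 0.979 in controls, 0.941 and 0.971 before treatment, and 0.911 and 0.971 after treatment (genes are not independent replicates).

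Levels are given as mean FPKM ± SD with n = 6 libraries. Changes are differences of log2(FPKM + 1) ± SE from limma, and this scale understates the change of genes with low values. List scores are given ± SD over the 6 libraries of their group, and score differences from controls ± the SD of the patient group. Adjusted p-values are Benjamini-Hochberg values over the 15903 genes tested, or over the 37 gene lists. The libraries of a group came from separate people, so the limma and permutation p-values measure the spread between people. After minus before, the same 6 people gave both groups, and only the patient blocks and sign-flip tests use that pairing. Camera with a preset correlation of 0.01 treats the genes of a list as nearly independent. The estimated correlation was 0.859 for hair shaft keratins and 0.925 for keratin-associated proteins, so preset camera p-values can be far too small.

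Scalp before treatment was compared with control scalp to find what distinguished affected skin. Genes of the hair fibre were far lower in the biopsies taken before treatment. KRTAP3-1, which encodes a keratin-associated protein that cross-links hair keratin filaments, was at 4312 ± 1444 FPKM in controls and 8.17 ± 11.4 FPKM before treatment. Lists of antigen presentation, cytotoxic lymphocyte, T cell and macrophage genes were called higher, as were those of sweat glands, vessels, nerve and connective tissue. None of these calls held with an estimated correlation (adjusted p from 0.278 to 0.519), and the genes past the threshold ran from 5 of 10 in the cytotoxic list to 12 of 12 in MHC class II. HLA-DRA was at 169 ± 27.0 FPKM in controls and 345 ± 77.2 FPKM before treatment. Across the transcriptome 3952 genes differed, 2729 higher and 1223 lower, of which 160 and 283 changed by at least 1 on the log2 scale.

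The lists of follicle genes held the steepest differences. All 37 of 37 hair keratin-associated proteins were lower (37 adjusted over the list alone), with a median log2 change of -8.65 (camera adjusted p = 1.33e-50). Of the hair shaft keratins, 16 of 17 (17 adjusted over the list alone) were lower, with a median of -7.27 (camera adjusted p = 1.43e-26). Among genes of the inner root sheath, the layer that moulds the growing shaft, 10 of 11 (10 adjusted over the list alone) were lower, with a median of -5.01 (camera adjusted p = 3.64e-16). Regulators of the hair matrix were lower in 17 of 20 (18 adjusted over the list alone), with a median of -1.74 (camera adjusted p = 3.14e-21). For each of these 4 lists the adjusted p was 0.0613 with an estimated correlation. The 8 largest falls were all keratin-associated proteins, KRTAP3-1, KRTAP9-8, KRTAP9-9, KRTAP9-4, KRTAP9-2, KRTAP3-3, KRTAP1-5 and KRTAP9-3, with log2 changes from -9.45 to -9.21. The KRTAP9 genes are near-identical copies, so the split of reads among them is uncertain. The shaft keratin KRT36 fell from 9.72 ± 2.84 to 0.118 ± 0.0904 FPKM. KRT25, a keratin of the inner root sheath, was at 779 ± 118 FPKM in controls and 23.5 ± 25.9 FPKM before treatment. LEF1, the transcription factor that carries WNT signals in the matrix, fell by 1.89 on the log2 scale (limma adjusted p = 2.31e-05). Hair genes held 8.94% ± 2.66 of the summed FPKM in controls and 0.144% ± 0.0483 before treatment (exact permutation p = 0.00216, the smallest that 6 against 6 libraries can give). Summed FPKM overweights short genes, and weighted by exon length the shares were 3.05% ± 0.920 and 0.116% ± 0.0189 (exact p = 0.00216).

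Other follicle lists moved less uniformly. The bulge and outer root sheath list had 4 members higher and 5 lower of 15 (5 and 5 adjusted over the list alone) and was not called (camera adjusted p = 0.0743), except without control replicate 3 (0.0413). Its score per library was lower by 0.42 ± 0.20 (SD among before-treatment libraries) in 6 of 6 libraries (exact permutation adjusted p = 0.00534). The stem cell receptor LGR5 changed by -2.22 ± 0.29, whereas KRT19, a keratin that sweat glands also express, changed by 1.98 ± 0.25. The dermal papilla list had 2 members higher and 3 lower of 14 (camera adjusted p = 0.443). Melanocyte genes were lower as a list, with 5 of 14 lower (7 adjusted over the list alone) and a median of -0.63 (camera adjusted p = 8.97e-04, and adjusted p = 0.342 with an estimated correlation). PMEL, which forms the fibrils on which pigment is laid down, was at 57.8 ± 14.3 FPKM in controls and 22.9 ± 8.69 FPKM before treatment. SOX10, which Schwann cells also express, was the 1 melanocyte gene that was higher (log2 change 1.06 ± 0.14).

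Most genes of antigen presentation and of macrophages and dendritic cells were higher before treatment. All 12 of 12 genes of MHC class II presentation were higher (12 adjusted over the list alone), with a median log2 change of 0.96 (camera adjusted p = 4.19e-07, and adjusted p = 0.278 with an estimated correlation). MHC class I presentation was higher in 12 of 14 (12 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 1.23e-05, and adjusted p = 0.285 with an estimated correlation). B2M, the light chain of class I molecules, was at 1445 ± 201 FPKM in controls and 2862 ± 694 FPKM before treatment. HLA-DRB5 (2.43 ± 0.63) and HLA-DQB1 (2.10 ± 0.41) were among the 8 largest rises, and HLA genes share sequence with one another, so their separate levels are uncertain. The donors' HLA types were not used, and patients and controls were different people. Inherited HLA differences can therefore not be told apart from changes in level for these genes. Macrophage and dendritic cell markers were higher in 13 of 17 (15 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 5.35e-05, and adjusted p = 0.278 with an estimated correlation). The monocyte receptor CD14 rose from 6.83 ± 0.793 to 12.2 ± 1.32 FPKM, and CD1B, which presents lipids on dendritic cells, rose from 1.22 ± 0.876 to 4.49 ± 1.33 FPKM.

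Several lymphocyte and cytokine lists were also called higher. Cytotoxic lymphocyte genes were higher in 5 of 10 (9 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 0.00572, and adjusted p = 0.473 with an estimated correlation), a call that ended with a filter of 5 FPKM (adjusted p = 0.289). They included granzyme A, GZMA (1.31 ± 0.38), perforin, PRF1 (0.84 ± 0.23), the activating receptor KLRK1 (0.94 ± 0.26) and the chemokine CCL5 (1.70 ± 0.45). T cell genes were higher in 7 of 10 (8 higher and 1 lower adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.0258, and adjusted p = 0.519 with an estimated correlation). The proximal T cell kinases LCK (0.93 ± 0.22) and ZAP70 (0.89 ± 0.26) were higher. The T cell call ended with a filter of 5 FPKM (adjusted p = 0.241) and without before-treatment replicate 3 (0.0518). The interferon gamma response was higher in 5 of 15 (7 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 0.00245, and adjusted p = 0.473 with an estimated correlation). CIITA, the master regulator of class II genes, and the adhesion molecule ICAM1 each rose (0.82 ± 0.18 and 0.85 ± 0.18). The gamma-chain cytokine and JAK-STAT list was higher in 11 of 19 (12 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.00245, and adjusted p = 0.285 with an estimated correlation). It included STAT5A (0.84 ± 0.17), STAT4 (0.61 ± 0.11) and JAK3 at 2.0 ± 0.762 FPKM in controls and 3.76 ± 0.952 FPKM before treatment (limma adjusted p = 0.0187). JAK1 changed by 0.22 ± 0.08 with a limma adjusted p of 0.0498, which became 0.313 after median-ratio rescaling, 0.0915 after quantile normalization, 0.0603 with no filter, 0.0556 without trend or robust settings and 0.0687 with only the groups compared. It passed the threshold in only 5 of the 18 fits that left out 1 library, those without control replicate 5, before-treatment replicate 1, 3 or 4, or after-treatment replicate 6 (adjusted p up to 0.115 in the others). Type 2 cytokine genes were higher in 5 of 10 (8 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.0105, and adjusted p = 0.278 with an estimated correlation), a call that ended with no filter (adjusted p = 0.0750). Their chemokines CCL13 and CCL22 changed by 1.96 ± 0.36 and 0.90 ± 0.15, and CCL18 by 2.37 ± 0.81. The call of CCL18 ended after median-ratio rescaling (adjusted p = 0.0525), with a pseudocount of 0.1 (0.0731) and in 12 of the 18 fits without 1 library (adjusted p up to 0.0929), all but those without control replicate 2, before-treatment replicate 2, or after-treatment replicate 1, 2, 3 or 4. Mast cell markers were higher in 3 of 9 (6 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.0371, and adjusted p = 0.501 with an estimated correlation). That call ended without control replicate 4 or 5 or before-treatment replicate 3, 5 or 6 (adjusted p from 0.0518 to 0.0871).

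The remaining immune lists were not called by camera run on the limma fit. The limma camera adjusted p was 0.129 for regulatory T cells and checkpoints (4 of 8 genes higher), 0.187 for the type I interferon response (1 of 20), 0.964 for NKG2D ligands (1 of 5) and 0.849 for B and plasma cells (1 of 4). After median-ratio rescaling the regulatory T cell list (adjusted p = 0.0434) and the type I list (adjusted p = 0.0289) passed the threshold. CD8A (0.88 ± 0.34, limma adjusted p = 0.0697), CXCL9 (1.54 ± 0.75, 0.146), CXCL10 (1.87 ± 0.88, 0.132) and MX1 (0.52 ± 0.48, 0.458) did not pass it. GZMB, ICOS and CXCL11 lay below the expression filter and were not tested.

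Lists of other tissues in the biopsy were called higher before treatment. Eccrine sweat gland genes were higher in 10 of 13 (12 adjusted over the list alone), with a median of 1.53 (camera adjusted p = 4.85e-05, and adjusted p = 0.278 with an estimated correlation). The water channel AQP5 was at 25.9 ± 9.30 FPKM in controls and 125 ± 41.6 FPKM before treatment, the antimicrobial sweat peptide DCD at 1218 ± 1016 and 5026 ± 4464 FPKM, and the ductal keratin KRT7 at 15.6 ± 6.78 and 84.6 ± 59.6 FPKM. The DCD call ended with only the groups compared (0.0573). PIP (2.40 ± 0.75) and DHRS2 (2.33 ± 0.76) completed the 8 largest rises, and both calls depended on single libraries. The PIP call ended without control replicate 1, 2 or 4 or before-treatment replicate 1, 4 or 5 (adjusted p up to 0.0597), and the DHRS2 call without control replicate 1, 3 or 6 or before-treatment replicate 5 (up to 0.0758). With only the groups compared both ended (0.0613 and 0.0532), and with a pseudocount of 10 the DHRS2 call did (0.0905). Nerve and Schwann cell genes were higher in 8 of 11 (10 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 2.70e-04, and adjusted p = 0.278 with an estimated correlation). Endothelial genes were higher in 8 of 11 (11 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.00193, and adjusted p = 0.443 with an estimated correlation). Fibroblast and matrix genes were higher in 8 of 15 (8 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.00749, and adjusted p = 0.473 with an estimated correlation), including the collagen-binding proteoglycan DCN (0.84 ± 0.11). Smooth muscle (5 of 12, median 0.60, camera adjusted p = 0.0248, and adjusted p = 0.519 with an estimated correlation), adipocyte (3 of 13, median 0.99, camera adjusted p = 0.0287, and adjusted p = 0.552 with an estimated correlation) and skeletal muscle (3 of 7, median 0.57, camera adjusted p = 0.0485, and adjusted p = 0.278 with an estimated correlation) were also called higher. The smooth muscle call ended without control replicate 5 or before-treatment replicate 6 (adjusted p up to 0.0756), the adipocyte call without control replicate 6 or before-treatment replicate 1 or 2 (up to 0.137), and the skeletal muscle call in 12 of the 18 fits without 1 library (up to 0.0783). It stayed only without control replicate 2, before-treatment replicate 1, 2 or 5, or after-treatment replicate 2 or 4. With a filter of 5 FPKM the adipocyte (0.0865) and skeletal muscle (0.666) calls ended, and the latter also with a pseudocount of 10 (0.0679) and with only the groups compared (0.0721).

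Keratinocyte lists split. Epidermal activation genes, the keratins and S100 proteins of growing or wounded epithelium, were lower in 5 of 15 (5 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 1.01e-06, and adjusted p = 0.278 with an estimated correlation). Whole biopsies hold epidermis and follicle together, so the tissue in which these genes fell is not known. KRT16 was at 1282 ± 204 FPKM in controls and 225 ± 84.7 FPKM before treatment. Proliferation genes were lower in 12 of 17 (13 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.04e-09, and adjusted p = 0.278 with an estimated correlation), including MKI67 (-0.53 ± 0.12). The immediate early and heat shock list was lower (1 of 15 lower, camera adjusted p = 0.00288, and adjusted p = 0.443 with an estimated correlation). Not called were epidermal differentiation with 2 genes higher and 1 lower of 19 (limma camera adjusted p = 0.849), sebaceous gland with 0 of 20 higher (adjusted p = 0.0948), cholesterol synthesis with 1 of 14 (adjusted p = 0.709) and blood with 0 of 3 (adjusted p = 0.413). The sebaceous list passed the threshold after median-ratio rescaling (adjusted p = 0.0134) and after quantile normalization (0.00648), and without control replicate 5 or before-treatment replicate 3, 5 or 6 (from 0.0119 to 0.0479). In NKG2D ligand, dermal papilla, cholesterol synthesis and epidermal differentiation the sign of the median, mean and test differed.

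The alopecia areata disease activity index (ALADIN) sums 3 short lists taken from earlier work on the disease. Its hair keratin list was lower in 6 of 8 genes (7 lower and 1 higher adjusted over the list alone), with a median of -4.88 (camera adjusted p = 3.64e-10, and adjusted p = 0.0613 with an estimated correlation). DSG4 (-4.33 ± 0.38), HOXC13 (-2.58 ± 0.30), KRT31 (-7.72 ± 0.90), KRT32 (-5.43 ± 0.57), KRT33B (-8.38 ± 1.02) and KRT82 (-5.51 ± 0.58) were lower, and PKP1 (-0.46 ± 0.18) and PKP2 (0.29 ± 0.11) did not pass the threshold. The cytotoxic list, with 1 of 2 tested members higher (limma camera adjusted p = 0.175), and the interferon list, with 0 of 4 (adjusted p = 0.332), were not called. Scored per library as the mean of all their members, the lists all differed from controls. The scores include genes below the expression filter, with 4 cytotoxic and 5 interferon members, so they do not cover the same genes as camera. The differences were -4.26 ± 0.18 for the hair keratin score (exact permutation adjusted p = 0.00534), 0.69 ± 0.39 for the cytotoxic score (exact adjusted p = 0.00890) and 1.03 ± 0.99 for the interferon score (exact adjusted p = 0.0348; SD over n = 6 libraries). Over all 37 lists, 18 scores were higher and 8 lower than in controls. The regulatory T cell score, over 12 members, was higher (0.37 ± 0.19, exact adjusted p = 0.0120), although camera, which tested 8 of them, did not call that list. Of the lists camera called, the epidermal activation (-1.21 ± 1.19, exact adjusted p = 0.0564), adipocyte (0.89 ± 1.06, 0.113) and immediate early (-0.43 ± 0.59, 0.310) scores did not pass.

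Camera with a preset correlation of 0.01 called 25 of the 37 lists, 16 higher and 9 lower, and with an estimated correlation it called none. Fry, which asks only whether a list moved in a single direction, called 25, including hair shaft keratin (adjusted p = 8.58e-06). Of 98 called list members with the smallest p in their lists, 82 kept their call without any single library. The share of higher genes among the calls was 69.1% as deposited, 46.8% after median-ratio rescaling and 58.9% after quantile normalization, so the balance of directions rests on the scaling, while the median change of all genes was 0.09, 0.01 and 0.04.

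**Figure D1:**
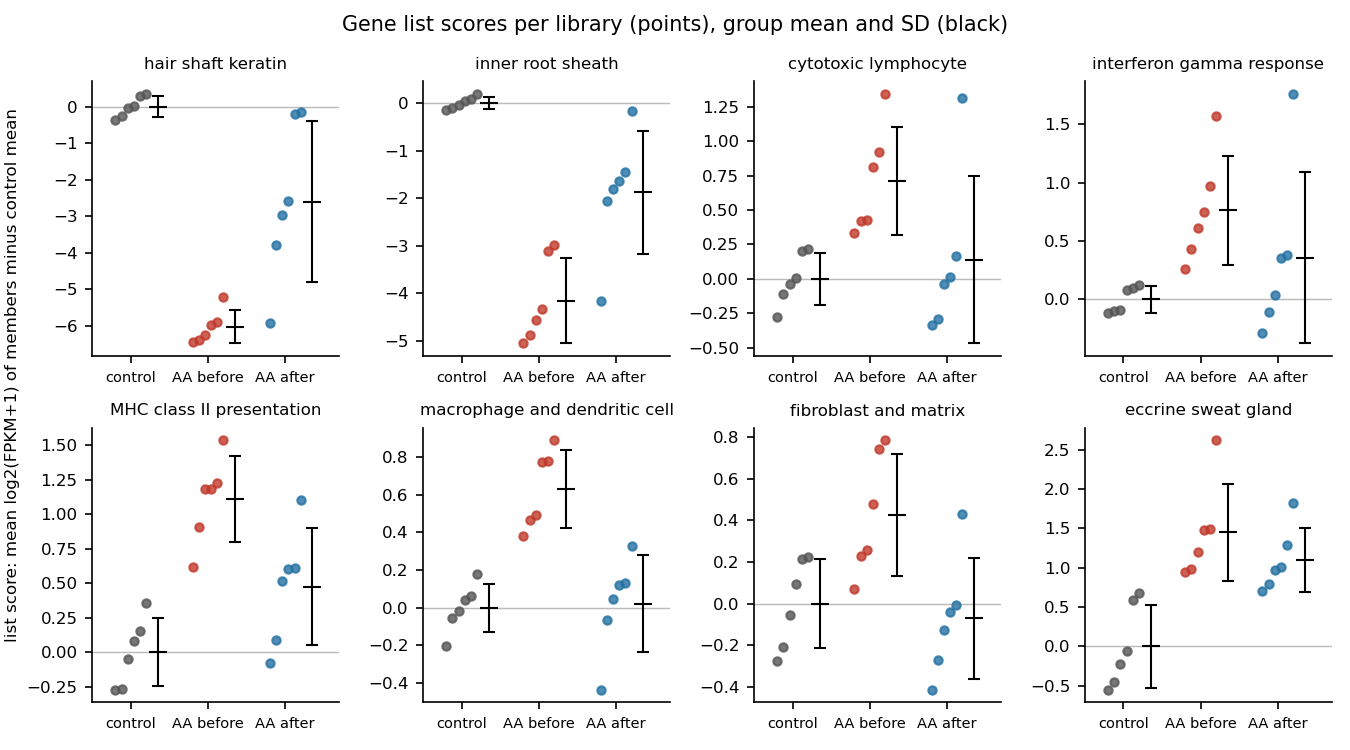
Scores of 8 gene lists in each library (points; mean log2(FPKM + 1) of the list's members minus the control mean), with the group mean and SD in black, for controls, alopecia areata before and alopecia areata after treatment, 6 libraries each. The hair shaft keratin score averaged -6.03 before and -2.60 after treatment, where the libraries spread most widely.

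The biopsies after treatment were compared with those before treatment to ask what changed during tofacitinib. Hair fibre genes were higher on average after treatment, with wide spread between patients (list adjusted p = 0.192 with an estimated correlation). KRTAP19-5 was at 5.18 ± 12.7 FPKM before and 1015 ± 1573 FPKM after treatment, and KRT31 at 8.20 ± 5.02 and 382 ± 426 FPKM. Lists of macrophage and dendritic cell, MHC class II and dermal matrix genes were called lower, with 7 of 17, 6 of 12 and 5 of 15 genes past the threshold. None of these calls held with an estimated correlation (adjusted p = 0.192, 0.281 and 0.281). CD163 was at 3.38 ± 0.932 FPKM before and 1.38 ± 0.478 FPKM after treatment, and DCN at 658 ± 122 and 349 ± 33.0 FPKM. In all 1276 genes differed, 447 higher and 829 lower (limma, adjusted p under 0.05). With the patient as a block 1291 differed, 351 higher and 940 lower, and 769 of these were among the 1276. The blocked count was 3, 0 and 5 without replicate 2, 5 or 6 and 580 without replicate 3. Of 64 named genes called, 20 were still called when only the 12 patient libraries were fitted without the block (adjusted p up to 0.0986). Of 53 named genes called with the block, 51, 0, 25, 41, 0 and 3 were still called without replicate 1, 2, 3, 4, 5 or 6.

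The hair lists were higher after treatment, but the calls of their single genes depended on the fit. Of 25 named hair genes called, 4 were called when only the 12 patient libraries were fitted (adjusted p up to 0.0986), 0 when the patient was also a fixed block (0.0547 to 0.115) and 25 with the patient as a random block over all 18 libraries (up to 0.00884). Keratin-associated proteins were higher in 34 of 37 (37 adjusted over the list alone) and in 0 with the patient block. The median change was 5.06 (camera adjusted p = 1.15e-37, and adjusted p = 0.192 with an estimated correlation). Hair shaft keratins were higher in 14 of 17 (17 adjusted over the list alone) and in 0 with the block, with a median of 4.05 (camera adjusted p = 9.82e-19, and adjusted p = 0.192 with an estimated correlation). Inner root sheath genes were higher in 7 of 11 (10 adjusted over the list alone) and in 0 with the block, with a median of 2.68 (camera adjusted p = 7.96e-10, and adjusted p = 0.192 with an estimated correlation). Hair matrix regulators were higher in 8 of 20 (11 adjusted over the list alone) and in 2 with the block, with a median of 0.61 (camera adjusted p = 9.63e-09, and adjusted p = 0.221 with an estimated correlation). With the block camera still called these 4 lists higher (adjusted p from 8.24e-21 to 8.78e-06). The 8 largest rises were KRTAP19-5, KRTAP19-1, KRTAP3-1, KRTAP2-1, KRTAP1-5, KRTAP1-3, KRTAP4-7 and KRTAP3-3, with log2 changes from 6.65 to 5.37, higher in 5 of 6 patients, and the blocked adjusted p lay between 0.0613 and 0.0946. S100A3, a calcium-binding protein of the hair cuticle, was higher in 6 of 6 patients (3.26 ± 0.54, limma adjusted p = 0.0147, blocked 0.0555). Among the ALADIN hair genes, DSG4, HOXC13, KRT31, KRT32, KRT33B and KRT82 rose by 1.01 to 4.59, with blocked adjusted p from 0.0601 to 0.0876, and PKP2 changed by -0.32 ± 0.11, past the threshold with the block (0.0432), with array weights and without after-treatment replicate 1. That list was called higher (camera adjusted p = 7.82e-06, and adjusted p = 0.192 with an estimated correlation). HOXC13, which switches on hair keratin genes, kept its call in only 3 of the 18 fits without 1 library, those without control replicate 2 or after-treatment replicate 1 or 6 (adjusted p up to 0.0980 in the others), and lost it with no filter (0.0559) and with a pseudocount of 10 (0.0515). The call of the hair desmoglein DSG4 ended with a pseudocount of 10 (0.110) and without before-treatment replicate 5 or 6 or after-treatment replicate 2 (up to 0.0643). Hair genes held 2.96% ± 3.81 of the summed FPKM after treatment, against 0.144% ± 0.0483 before (exact permutation p = 0.0108, and 0.0625 in the exact sign-flip test within patients). Weighted by exon length the shares were 0.956% ± 1.08 and 0.116% ± 0.0189 (exact p = 0.0152, exact sign-flip p = 0.0625). After-treatment replicates 3 and 5 held 9.09% and 6.39% of their summed FPKM in hair genes, and the other after-treatment libraries 0.108% to 0.989%.

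Pigment cell genes were also called higher as a list. The melanocyte list was higher, with 2 of 14 genes past the threshold (4 adjusted over the list alone, 6 with the block) and a median of 0.49 (camera adjusted p = 1.15e-05, and adjusted p = 0.281 with an estimated correlation). PMEL rose from 22.9 ± 8.69 to 52.3 ± 21.0 FPKM and tyrosinase, TYR, from 4.87 ± 2.39 to 11.4 ± 6.07 FPKM, and the TYR call ended with no filter (0.0602) and with a pseudocount of 10 (0.0629). The proliferation list was called higher with 1 of 17 genes past the threshold, the mitotic kinase AURKB (0.67 ± 0.14, list camera adjusted p = 2.07e-04, and adjusted p = 0.558 with an estimated correlation). The epidermal activation list was called higher with 1 of 15 genes, KRT16 (1.05 ± 0.29, blocked adjusted p = 0.0881), with camera adjusted p = 0.0470, and adjusted p = 0.687 with an estimated correlation. Its call ended after median-ratio rescaling (0.159), after quantile normalization (0.125), with a filter of 5 FPKM (0.0750), with only the groups compared (0.0646) and without control replicate 5 or 6, before-treatment replicate 2, 3 or 6, or after-treatment replicate 3, 4 or 5 (adjusted p up to 0.445).

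Lists of antigen-presenting cell genes were called lower after treatment. Macrophage and dendritic cell markers were lower in 7 of 17 (15 adjusted over the list alone), 10 with the block, with a median of -0.66 (camera adjusted p = 4.56e-08, and adjusted p = 0.192 with an estimated correlation). The scavenger receptor CD163 (-0.88 ± 0.16), the growth factor receptor CSF1R (-0.74 ± 0.15), the mannose receptor MRC1 (-0.65 ± 0.10) and CD1B (-1.13 ± 0.26) were each lower in 6 of 6 patients. CD1E (-1.18 ± 0.24) and CD1C (-1.13 ± 0.33), which handle lipid antigens in dendritic cells, were among the 8 largest falls, and the CD1C call ended after quantile normalization (adjusted p = 0.0581), with no filter (0.0582), with a pseudocount of 0.1 (0.0515) and in 12 of the 18 fits without 1 library (up to 0.111), all but those without control replicate 1, 2, 3 or 6 or before-treatment replicate 1 or 4. MHC class II genes were lower in 6 of 12 (10 adjusted over the list alone), 9 with the block, with a median of -0.64 (camera adjusted p = 7.82e-06, and adjusted p = 0.281 with an estimated correlation). HLA-DRA was at 345 ± 77.2 FPKM before and 208 ± 56.5 FPKM after treatment. MHC class I was lower as a list with 0 of 14 genes past the threshold (1 with the block, B2M, adjusted p = 0.0325), with camera adjusted p = 0.0382, and adjusted p = 0.687 with an estimated correlation. That call ended with only the groups compared (0.0643) and without before-treatment replicate 1, 3 or 5 or after-treatment replicate 2, 3, 4 or 5 (adjusted p from 0.0508 to 0.175).

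The cytokine and lymphocyte lists were also called lower. The gamma-chain cytokine and JAK-STAT list fell in 4 of 19 (12 adjusted over the list alone), 6 with the block, with a median of -0.34 (camera adjusted p = 9.60e-06, and adjusted p = 0.192 with an estimated correlation). Among them were JAK2 (-0.47 ± 0.10), the shared receptor chain IL2RG (-0.76 ± 0.22) and the T cell survival cytokine IL7 (-0.52 ± 0.12). The IL2RG call ended after quantile normalization (adjusted p = 0.0579) and with no filter (0.0589). Of the drug's main targets, JAK1 fell from 39.5 ± 4.37 to 30.9 ± 2.71 FPKM (limma adjusted p = 0.0203, blocked 0.0348), a call that ended without before-treatment replicate 6 or after-treatment replicate 2 (up to 0.0522), and JAK3 was at 3.76 ± 0.952 and 2.44 ± 1.09 FPKM (adjusted p = 0.116). T cell genes were lower in 2 of 10 (6 adjusted over the list alone), 3 with the block, with a median of -0.62 (camera adjusted p = 6.72e-04, and adjusted p = 0.558 with an estimated correlation). They included CD247, the signalling chain of the T cell receptor (-0.65 ± 0.18, blocked adjusted p = 0.0564), whose call ended after quantile normalization (0.0537). In the cytotoxic list 0 of 10 (2 adjusted over the list alone) were lower, but 8 were with the block, and the median was -0.81 (camera adjusted p = 0.00214, and adjusted p = 0.558 with an estimated correlation). That list call ended with a filter of 5 FPKM (adjusted p = 0.214). Examples with their blocked adjusted p were GNLY (-0.93 ± 0.31, 0.0290), KLRK1 (-0.86 ± 0.26, 0.0269), GZMA (-1.0 ± 0.38, 0.0444), CD8A (-0.65 ± 0.34, 0.0348) and PRF1 (-0.54 ± 0.23, 0.0364), each lower in 6 of 6 patients. In the blocked fit none of these 5 was called without replicate 2, 5 or 6 (adjusted p from 0.0815 to 0.127), and 2 were without replicate 3 (up to 0.0657). A single after-treatment library, replicate 1, stood apart on the cytotoxic score, at 1.32 against 0.16 or below in the others. The interferon gamma response was lower in 2 of 15 (2 adjusted over the list alone), 3 with the block, with a median of -0.52 (camera adjusted p = 0.0355, and adjusted p = 0.687 with an estimated correlation), and its call ended with a filter of 5 FPKM (0.0750), with a pseudocount of 10 (0.0770), with only the groups compared (0.0643) and without before-treatment replicate 1 or after-treatment replicate 2, 3, 4 or 5 (adjusted p from 0.0841 to 0.189). CXCL9 (-0.72 ± 0.75), CXCL10 (-1.02 ± 0.88) and MX1 (-0.01 ± 0.48) did not pass the threshold with or without the block. The type 2 list was lower in 3 of 10 (4 adjusted over the list alone), 2 with the block, with a median of -0.39 (camera adjusted p = 0.0279, and adjusted p = 0.391 with an estimated correlation). CCL13, which attracts monocytes and eosinophils, was at 21.0 ± 6.94 FPKM before and 7.49 ± 3.61 FPKM after, and its call ended without before-treatment replicate 5 or 6 or after-treatment replicate 2 or 3 (up to 0.0709). The list call itself ended with no filter (adjusted p = 0.374) and without before-treatment replicate 3 (0.0544).

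The dermal matrix list was called lower as well. Fibroblast and matrix genes were lower in 5 of 15 (10 adjusted over the list alone), 8 with the block, with a median of -0.46 (camera adjusted p = 7.75e-06, and adjusted p = 0.281 with an estimated correlation). DCN (-0.90 ± 0.11), the collagen cross-linking enzyme LOX (-0.93 ± 0.22), the scavenger receptor SCARA5 (-0.97 ± 0.20), CCDC80 (-0.93 ± 0.21) and complement C3 (-0.94 ± 0.24) were among the 8 largest falls, each lower in 6 of 6 patients. All 8 of those falls kept their calls with the patient block (adjusted p from 0.0211 to 0.0455). In the blocked fit without replicate 2, 5 or 6 none of the 8 was called (adjusted p from 0.0595 to 0.131), and without replicate 3 only 4 were (up to 0.0681). The calls of LOX (0.0536) and CCDC80 (0.0508) ended without after-treatment replicate 2, and that of C3 without before-treatment replicate 5 or 6 or after-treatment replicate 2 (up to 0.0702).

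The other lists were not called between the treatment times. Their camera adjusted p-values were 0.794 for the type I interferon response, 0.0977 for regulatory T cells, 0.748 for NKG2D ligands, 0.863 for B and plasma cells, 0.128 for the bulge, 0.698 for the dermal papilla, 0.270 for the sebaceous gland, 0.571 for cholesterol synthesis, 0.255 for the eccrine gland, 0.845 for epidermal differentiation, 0.794 for adipocytes, 0.251 for endothelium, 0.136 for nerve, 0.617 for immediate early genes, 0.571 for blood and 0.640 for the ALADIN interferon list. Mast cell (0.117), skeletal muscle (0.214), smooth muscle (0.0699) and ALADIN cytotoxic (0.235) passed the threshold with the patient block, at 0.0119, 0.0475, 0.0106 and 0.0402, and mast cell also after quantile normalization (0.0494). In the blocked fit without replicate 6 the type I interferon list was called lower (0.00205). Without the block, 9 of the lists not called passed when 1 library was left out. They were smooth muscle without control replicate 2, before-treatment replicate 1 or 6 or after-treatment replicate 2 or 3 (adjusted p from 0.00363 to 0.0471), and mast cell without before-treatment replicate 1 (0.00865) or after-treatment replicate 6 (0.0401). Without before-treatment replicate 1 sebaceous gland passed (0.0355), without before-treatment replicate 5 nerve (0.0385), and without after-treatment replicate 2 eccrine gland (0.0264). Without after-treatment replicate 1 regulatory T cells (0.0265), bulge (0.0373), endothelium (0.0338) and ALADIN cytotoxic (0.0265) passed. Scored per library, 0 of the 37 lists passed (smallest exact permutation adjusted p = 0.0534, with an unadjusted p under 0.05 in 14). The hair shaft score rose by 3.42, from -6.03 ± 0.46 to -2.60 ± 2.21 (exact p = 0.00649, adjusted 0.0534), in 5 of 6 patients (exact sign-flip p = 0.0625). The macrophage and dendritic cell score fell by 0.61 in 6 of 6 patients (exact p = 0.00216, adjusted 0.0534; exact sign-flip p = 0.0312, the smallest 6 pairs can give).

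Camera called 17 lists, 8 higher and 9 lower, and none with an estimated correlation. Fry, run without the patient block, called 12. Of 41 called list members with the smallest p in their lists, 23 kept their call without any single library and 24 with the patient block. The gene counts changed with the libraries fitted: 249 genes differed when only the 12 patient libraries were fitted, 745 without the patient sampled at week 36, and 620, 470, 320, 289 and 675 without before-treatment replicate 2, 5 or 6 or after-treatment replicate 2 or 5. Without before-treatment replicate 1 the higher genes numbered 283, and without after-treatment replicate 3 the lower genes numbered 516. The share of higher genes was 35.0% as deposited, 57.3% after median-ratio rescaling and 37% after quantile normalization.

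**Figure D2:**
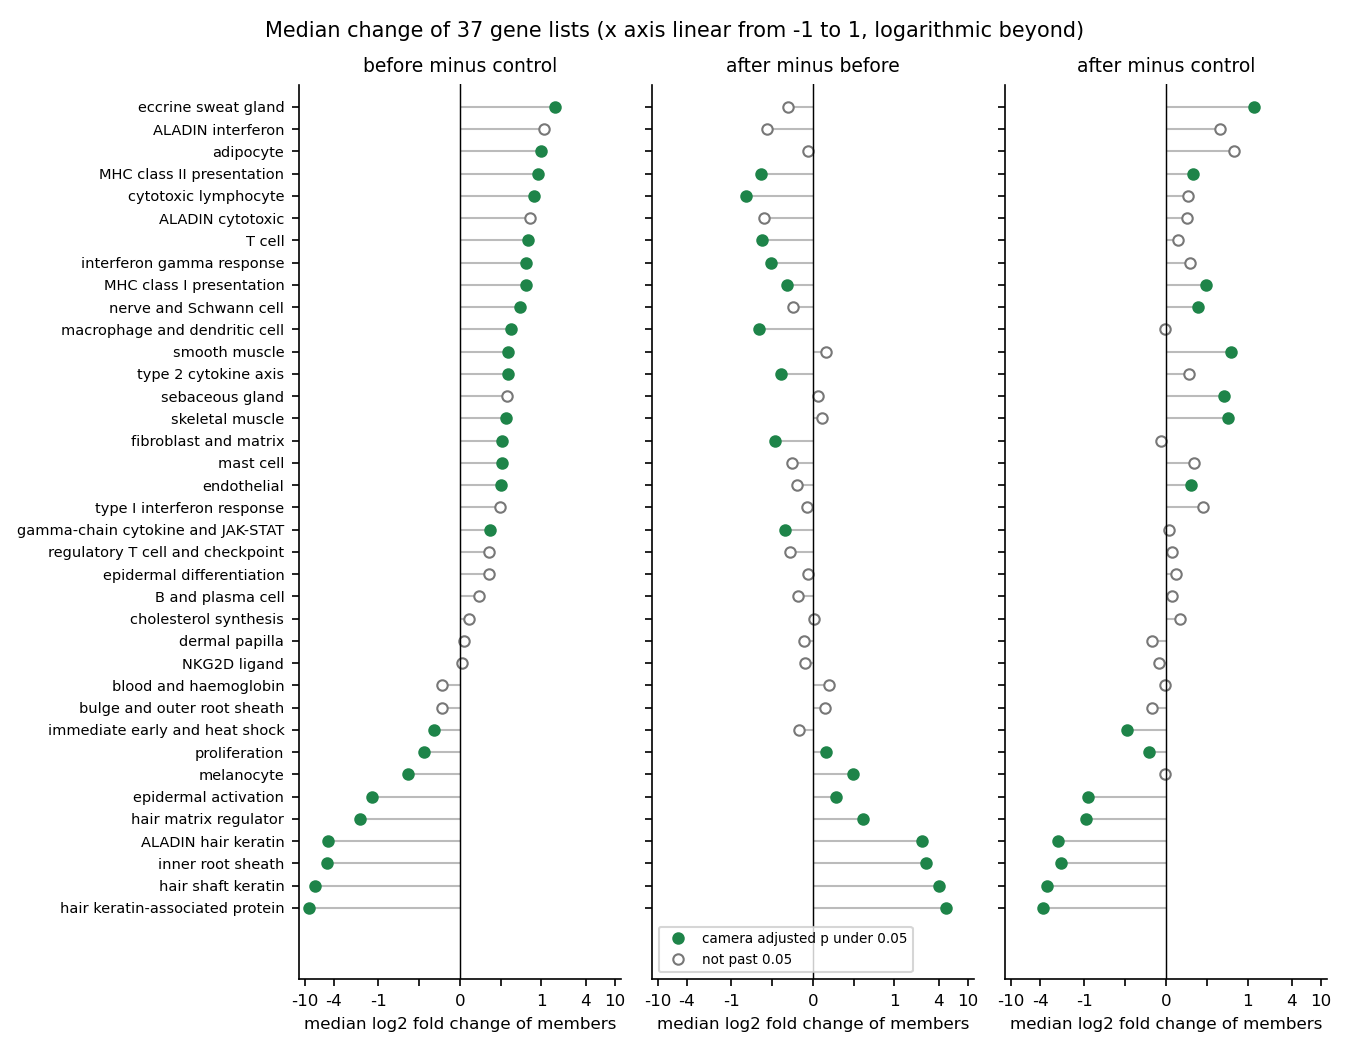
Median log2 change of the members of each of the 37 gene lists (x axis, linear between -1 and 1 and logarithmic beyond) in the comparisons before minus control, after minus before and after minus control. Filled points passed an adjusted p of 0.05 in camera with a preset correlation of 0.01, and no list passed with an estimated correlation. Hair keratin-associated proteins had medians of -8.65, 5.06 and -3.69.

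The biopsies after treatment were then compared with controls to ask how far they still differed. Hair fibre genes were lower on average than in controls (list adjusted p = 0.665 with an estimated correlation). The lists of sweat gland, smooth muscle, skeletal muscle and nerve genes were called higher, with 5 of 13, 7 of 12, 5 of 7 and 3 of 11 genes past the threshold. None of these calls held with an estimated correlation (adjusted p = 0.665, 0.665, 0.419 and 0.672). KRTAP9-8 was at 1827 ± 929 FPKM in controls and 336 ± 495 FPKM after treatment. AQP5 was at 25.9 ± 9.30 and 102 ± 36.7 FPKM. No call was made for the cytotoxic, T cell or macrophage lists, with medians of 0.27, 0.15 and -0.01. Hair scores varied among the after-treatment libraries. The hair shaft score was within the range of the controls in 2 of 6 after-treatment libraries and averaged -2.60 ± 2.21 (exact permutation p = 0.0152, adjusted 0.0623), and the keratin-associated protein score was within it in 2 of 6 and averaged -3.28 ± 2.90 (exact p = 0.0303, adjusted 0.102), so neither passed after adjustment. The inner root sheath (-1.88 ± 1.30), hair matrix (-1.14 ± 0.65) and ALADIN hair (-2.07 ± 1.39) scores did (exact adjusted p = 0.0133 each). So did eccrine (1.10 ± 0.41), skeletal muscle (0.38 ± 0.05) and nerve (0.48 ± 0.20) at the same adjusted p, and smooth muscle (0.73 ± 0.32) and MHC class I (0.50 ± 0.46) at an exact adjusted p of 0.0400. The scores of MHC class II, sebaceous gland, epidermal activation, endothelium, proliferation and immediate early genes, lists that camera called, did not pass (exact adjusted p from 0.102 to 0.191). In all 3793 genes differed, 2267 higher and 1526 lower, with 99 and 197 past 1 on the log2 scale.

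Keratin-associated proteins were lower in 32 of 37 (32 adjusted over the list alone), with a median of -3.69 (camera adjusted p = 2.98e-15, and adjusted p = 0.665 with an estimated correlation), and hair shaft keratins in 15 of 17 (15 adjusted over the list alone), with a median of -3.22 (camera adjusted p = 2.99e-09, and adjusted p = 0.665 with an estimated correlation). Inner root sheath genes were lower in 8 of 11 (10 adjusted over the list alone) (camera adjusted p = 3.26e-06, and adjusted p = 0.665 with an estimated correlation) and hair matrix regulators in 16 of 20 (17 adjusted over the list alone) (camera adjusted p = 4.58e-10, and adjusted p = 0.459 with an estimated correlation), among them MSX2 (-1.58 ± 0.31) and LEF1 (-1.29 ± 0.22). Of the 8 largest falls, 7 were KRTAP9 genes (KRTAP9-7, KRTAP9-8, KRTAP9-9, KRTAP9-6, KRTAP9-2, KRTAP9-3 and KRTAP9-4), with log2 changes from -4.34 to -4.01. The other, and the largest, was the small nucleolar RNA SNORA1 (-4.36 ± 1.5), whose call ended without any control library or without after-treatment replicate 1, 2, 4 or 5 (adjusted p up to 0.10), with no filter (0.0538), with a pseudocount of 0.1 (0.0504) and with array weights (0.0560). The ALADIN hair list was lower in 6 of 8 genes (camera adjusted p = 3.13e-05, and adjusted p = 0.459 with an estimated correlation), with KRT31 at 1799 ± 510.0 FPKM in controls and 382 ± 426 FPKM after treatment. Epidermal activation (4 of 15 lower, camera adjusted p = 0.00101, and adjusted p = 0.70 with an estimated correlation), proliferation (4 of 17, camera adjusted p = 0.00167, and adjusted p = 0.770 with an estimated correlation) and the immediate early list (4 of 15, camera adjusted p = 0.00140, and adjusted p = 0.665 with an estimated correlation) were lower. FOS, an immediate early transcription factor, was at 192 ± 186 FPKM in controls and 13.4 ± 7.59 FPKM after treatment. Its call ended after quantile normalization (0.0503), with no filter (0.0586), with a pseudocount of 0.1 (0.0513), with only the groups compared (0.0504) and with array weights (0.0886).

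Lists of gland, muscle and nerve genes were called higher. Eccrine genes were higher in 5 of 13 (8 adjusted over the list alone), with a median of 1.21 (camera adjusted p = 8.39e-04, and adjusted p = 0.665 with an estimated correlation). Smooth muscle genes were higher in 7 of 12 (9 adjusted over the list alone) (camera adjusted p = 3.81e-04, and adjusted p = 0.665 with an estimated correlation), with the smooth muscle actin ACTA2 at 127 ± 27.9 FPKM in controls and 237 ± 53.7 FPKM after treatment. Skeletal muscle was higher in 5 of 7 (5 adjusted over the list alone) (camera adjusted p = 0.00292, and adjusted p = 0.419 with an estimated correlation), a call that ended with a filter of 5 FPKM (0.168), and nerve in 3 of 11 (5 adjusted over the list alone) (camera adjusted p = 0.00828, and adjusted p = 0.672 with an estimated correlation). The 8 largest rises were MIR499, C2orf82 (2.29 ± 0.29), SYT8 (1.99 ± 0.51), KRT7 (1.96 ± 0.35), the fast muscle troponin TNNI2 (1.93 ± 0.48), AQP5 (1.93 ± 0.25), LRRC26 (1.72 ± 0.39) and the suprabasal keratin KRT2 (1.65 ± 0.57). MIR499, a short microRNA gene, was listed at 0 in all 6 controls and averaged 77.0 FPKM after treatment, so no fold is given. Its lowest after-treatment library was also at 0, and the others lay between 5.86 and 7.29 on the log2(FPKM + 1) scale. How many reads lie behind these values is unknown. The KRT2 call ended after median-ratio rescaling (0.0537), with no filter (0.0557), with only the groups compared (0.0658) and without control replicate 1, 3, 4 or 5, before-treatment replicate 1, 2, 3 or 5, or after-treatment replicate 2, 5 or 6 (adjusted p up to 0.102). MHC class I genes were higher in 7 of 14 (8 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.00167, and adjusted p = 0.715 with an estimated correlation), and MHC class II genes in 3 of 12 (3 adjusted over the list alone) (camera adjusted p = 0.0443, and adjusted p = 0.850 with an estimated correlation). The class II call ended with a filter of 5 FPKM (0.0785) and without control replicate 3, 5 or 6, before-treatment replicate 1, or after-treatment replicate 1, 4, 5 or 6 (adjusted p up to 0.140). Endothelium (1 of 11, camera adjusted p = 0.0267, and adjusted p = 0.850 with an estimated correlation) and sebaceous gland (2 of 20, camera adjusted p = 0.0110, and adjusted p = 0.915 with an estimated correlation) were called higher, calls that ended without control replicate 3, 4 or 5 or after-treatment replicate 1 or 6 for endothelium (up to 0.0926) and without control replicate 6 for sebaceous gland (0.0804). The adipocyte list passed after median-ratio rescaling (0.0229) or quantile normalization (0.0312), and without control replicate 1 or 2, before-treatment replicate 2 or 4, or after-treatment replicate 3 or 4 (from 0.0171 to 0.0451). The type I interferon list passed without control replicate 6 (0.0381) or after-treatment replicate 2 (0.0110), and the interferon gamma list without after-treatment replicate 2 (0.0333).

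Lists with both signs or without calls included genes of T cells that were lower than in controls. CD6 (-0.84 ± 0.18), a T cell surface receptor, and the checkpoint receptor CTLA4 (-0.72 ± 0.16) were lower after treatment, while the costimulatory receptor TNFRSF18 was higher (0.97 ± 0.17). JAK1 (-0.13 ± 0.08, limma adjusted p = 0.241) and JAK3 (0.18 ± 0.20, 0.533) did not differ past the threshold. Camera called 16 lists, 8 in each direction, and none with an estimated correlation. Fry called 10. Of 67 called list members with the smallest p in their lists, 41 kept their call without any single library. The share of higher genes was 59.8% as deposited, 45.2% after median-ratio rescaling and 47.3% after quantile normalization. Without control replicate 6 the number of lower genes was 1010.

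Genes that differed before treatment moved back toward control levels after it. Of the 2729 genes higher before treatment, 372 were lower after treatment (142 under independence), and of the 1223 lower genes 218 were higher (34.4 under independence). In the same direction the overlaps were 2 and 1 genes, against 76.7 and 63.8 under independence. Both comparisons use the before-treatment libraries with opposite sign, so chance alone gives some opposite movement. Over the 3952 genes the slope of the after-treatment change on the before-treatment change was -0.52, and 80.2% of genes moved in the opposite direction. Genes with the largest changes weigh most in a slope. The keratin-associated proteins had medians of -8.65 and 5.06 in the 2 comparisons, and the slope was not computed without hair genes. With simulated unchanged libraries the slope averaged -0.03 and the opposite share 61.0%. The simulated sets called 5139 genes on average against the real 3952, so they do not match the data in full. The covariance was -0.239 against a simulated -0.0227. With different before-treatment libraries on each side the median slope was -0.51 (range -0.80 to -0.24). The opposite share then had a median of 76.5% (range 59.9% to 89.9%). Relative to controls, 1122 genes were higher and 762 lower at both times. These counts share the control libraries. With different controls on each side, a test chosen after the counts were seen, the median over 20 divisions was 70.5 higher and 77.5 lower genes, against 16.6 and 7.76 under independence, and the overlap exceeded independence in 20 of 20 divisions for each direction. The patients were still the same at both times.

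**Figure D3:**
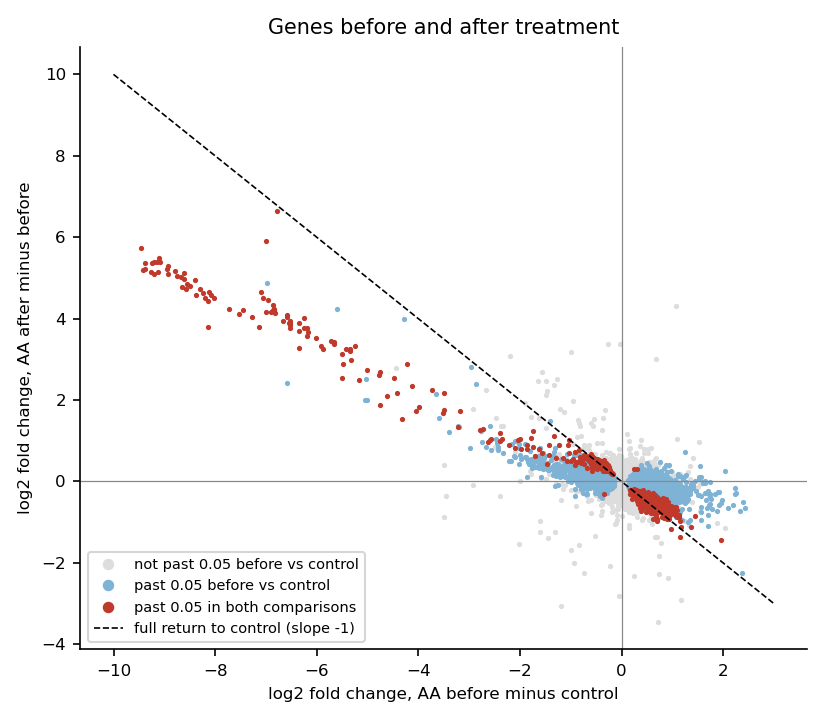
Log2 change after minus before treatment (y axis) against before treatment minus control (x axis), one point per gene. Of the genes called in the before-treatment comparison, 80.2% changed in opposite directions, and the slope was -0.52.

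The change in cytotoxic lymphocyte score was compared with the change in hair shaft score across the 6 patients. Pearson's r was -0.80 (exact permutation p = 0.05, adjusted 0.10) and Spearman's rho was -0.77 (exact p = 0.103). Without the 2 patients farthest from the median on the cytotoxic axis r was -0.69 (exact p = 0.333, 4 patients, whose 24 pairings give coarse p-values). Without replicate 1, the patient sampled at week 36, r was -0.43 (exact p = 0.558, 5 patients). Without replicate 4 or 6 r was -0.87 or -0.91 (exact p = 0.0333 each). For the ALADIN cytotoxic and hair keratin scores r was -0.92 (exact p = 0.0167, adjusted 0.0667) and -0.67 without the 2 farthest patients (exact p = 0.417). None of the 4 tests passed after adjustment.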

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

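The explanations weighed here, the counts of other splits and the choice of scale for single genes were tested or made after the results were seen. The interferon and follicle-share tests were first given firmer readings, and the more cautious ones used here were chosen after their values were seen. In each group of 6 libraries the highest or lowest value was called far from the others when its gap to the nearest library relative to the group's range exceeded the critical value of Dixon's test. Of 288 groups of values 30 passed, where chance gives about 1 in 20, or 14.4. Among list scores 13 of 111 passed (5.55 by chance) and among named genes on the log2(FPKM + 1) scale 17 of 162 (8.1 by chance). Genes were first tested on the FPKM scale, where 41 passed and 54 in all, and the log scale was adopted after that count was seen. HLA genes were not tested in this way.

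In a single after-treatment library several immune values stood far above the rest of its group. The scores were 1.32 for cytotoxic lymphocytes, 1.76 for the interferon gamma response, 1.58 for the ALADIN cytotoxic list and 3.11 for the ALADIN interferon list. On the log2(FPKM + 1) scale CD8A was at 2.68, GZMB at 3.34, CXCL10 at 6.12 and CXCL11 at 3.52. All 8 of these values came from the same library, which also had the lowest hair shaft score of its group, -5.93, against -3.80 or above in the others. It was after-treatment replicate 1, the only biopsy taken at week 36, so its patient and its week cannot be told apart. Its hair share of summed FPKM was the lowest of its group, 0.108%. The other 5 after-treatment libraries had hair shaft scores above every before-treatment library.

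Among before-treatment libraries the highest scores were far from the others for the type I interferon response (1.51), keratin-associated proteins (-6.20), melanocytes (0.16) and eccrine glands (2.62). The same held for single genes on the log2(FPKM + 1) scale, with DHRS2 at 7.45, KRTAP9-8 at 3.61, KRTAP9-9 at 2.81, KRTAP9-2 at 3.77, KRTAP9-7 at 2.43, KRTAP9-6 at 1.25, KRTAP1-5 at 4.04, KRTAP19-5 at 5.0 and MIR499 at 6.44, where KRTAP19-5 and MIR499 were listed at 0 in the other libraries. Among after-treatment libraries the lowest were epidermal differentiation (-0.68), DHRS2 (1.08), C3 (3.79) and MIR499 (0). Among controls the highest were skeletal muscle (0.23), blood (1.38) and SYT8 (3.32), and the lowest were sebaceous gland (-1.32) and proliferation (-0.28). No explanation was tested for these single libraries.

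Markers of tissue outside the follicle were higher before treatment than in controls, although no list passed with an estimated correlation. A smaller hair share of the total would raise the FPKM of every other gene alike. The hair share alone was taken out of each library, once weighted by exon length and once as a share of summed FPKM, which overweights short genes. Eccrine gland, endothelium and nerve still differed from controls both ways (exact permutation p up to 0.0173), which argues against this as the whole cause for them. Fibroblast (exact p = 0.0325) and smooth muscle (0.0433) differed with the first share only. With the second the fibroblast difference shrank from 0.43 to 0.30 (SD 0.29 before treatment both times, exact p = 0.0779) and that of smooth muscle from 0.53 to 0.40 (SD 0.37 both times, exact p = 0.0931), so for these lists it stays open. This test replaced an earlier one that had also made the summed FPKM equal, and the division into lists was made after its values were seen. A smaller share of follicle tissue in the biopsy could raise these markers too, and then all alike. Of 10 pairs of these lists, 0 differed in their rise past an adjusted p of 0.05. All of them had been called higher in the same libraries. Lists not called, such as epidermal differentiation, were left out, so the lack of a difference lends no support. The largest difference was 1.03 between eccrine gland and fibroblast (exact permutation p = 0.0260, adjusted 0.180), so this explanation stays open, as does a change in the tissues themselves.

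Camera called 8 immune lists lower after treatment with a preset correlation and 0 with an estimated correlation. Of the 37 list scores 0 passed (smallest exact adjusted p = 0.0534). Returning hair transcripts would lower the FPKM of every other gene. With the hair share of summed FPKM alone taken out, the mean of the 8 immune scores fell by 0.44 (exact permutation p = 0.0281), and by 0.46 with the share weighted by exon length or as deposited (exact p = 0.0260 each). The hair share so accounted for little of the measured fall. These 8 lists were chosen because camera called them lower in the same libraries, so these p-values lend no independent support. As deposited, the mean fell in 5 of 6 patients (exact sign-flip p = 0.0625). A larger share of follicle tissue could lower immune and other tissue markers alike. The mean of the immune scores fell by 0.46 and that of eccrine gland, endothelium, sebaceous gland, nerve and smooth muscle by 0.10. The difference was -0.36, lower in 5 of 6 patients (exact permutation p = 0.0649, exact sign-flip p = 0.0938). This set left out the fibroblast list, which was itself called lower. With fibroblast in place of sebaceous gland the other tissues fell by 0.21 in 6 of 6 patients (exact p = 0.0476), as this explanation predicts, and the difference was -0.25 (exact p = 0.143, exact sign-flip p = 0.156), so it stays open. The test had first used only the macrophage and dendritic cell list, the strongest of the pattern, and gave -0.51 (exact p = 0.0281, sign-flip p = 0.0625), which would have argued against the explanation. The mean of 8 lists replaced it for that reason. An effect of the drug on immune cells stays open as well, since there were no untreated patients with a later biopsy.

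Genes that differed before treatment moved back after it. Chance values of the before-treatment libraries, which both contrasts use, would give some of this. With different before-treatment libraries on each side the slope nearest to 0 among 20 divisions was -0.236. That argues against shared libraries as the whole cause of the slope, in which the strongly changed hair genes weigh most. The lowest opposite share in these divisions, 59.9%, lay within the simulated range of 59.6% to 62.1%, so the share of genes does not settle it. A return toward usual levels without treatment was not tested, because no patient was followed untreated, and it stays open.

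Other splits of the same libraries gave far fewer genes. Before treatment against control the real split gave 3952 genes and the highest of the others 2 (1 of 100 splits as large). After against before treatment gave 1276 against 237 (1 of 100), and 127 was the highest among the 32 splits that part every pair (1 of 32). After treatment against control gave 3793 against 1 (1 of 100). The counts against controls argue against chance. After against before treatment, 1 of 32 is the smallest share that splits parting every pair can give. There the blocked fit without 1 patient gave as few as 0 genes, so chance is not excluded for that count.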

How the results depend on the processing

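All alternatives in this part were planned, except the comparison with different controls on each side, which was chosen after the data were seen. The planned comparison with controls divided by the style of their sample names was not run, because the table's columns give only the group and could not be matched to the sample names. The causes of the changes below were not tested, except where fewer libraries or the choice of test is the alternative itself.

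Median-ratio rescaling gave 1596 higher genes before treatment against control, and 738 higher and 549 lower genes after against before treatment. Counts for after against before treatment depended most on the fit. Only the 12 patient libraries gave 249 genes (48 higher, 201 lower). Leaving out the patient sampled at week 36 gave 745 (264 and 481), and 23 lists called against 17 as reported. With the patient as a random block 3696 genes differed (1253 and 2443), and as a fixed replicate block 1291.

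Leaving out each library, or each patient with the replicate block, gave 0 to 1650 genes after against before treatment, 0 to 525 higher and 0 to 1210 lower. With the replicate block 3, 0 and 5 genes were called without replicate 2, 5 or 6 (4 of the last higher), 580 without replicate 3 (259 higher, 321 lower), and 231 higher genes without replicate 4. Without the block the ranges were 289 to 1523 genes, 125 to 525 higher and 163 to 1048 lower. Before treatment against control the ranges were 3122 to 4091 genes, 2094 to 2838 higher and 1028 to 1262 lower, and after treatment against control 2597 to 4086, 1561 to 2494 and 1010 to 1850. The lists called numbered 23 to 25 before treatment against control, 14 to 27 after against before treatment (27 without replicate 1 with the replicate block), and 14 to 18 after treatment against control. With an estimated correlation camera called 0, 0 and 0 lists in the 3 comparisons, and fry called 25, 12 and 10. The type I interferon list, not called lower or higher as reported, was called lower without replicate 6 with the replicate block (camera adjusted p = 0.00205). As reported its median log2 change was -0.07, and only the direction of the camera test, which did not call it, was up.

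The hair shaft score rose by 1.89 after treatment with a pseudocount of 10, past the threshold (exact adjusted p = 0.0481), but not as reported (0.0534) or in the other settings (0.0534 to 0.0641). Against controls it did not pass as reported (-2.60, exact adjusted p = 0.0623), with z-scores (0.107) or with pseudocounts of 0.1 (0.0641) or 10 (0.0534), and passed only from the median of members (-3.03, exact adjusted p = 0.0267). With pairs kept as a replicate block the exact sign-flip p was 0.03125 for the cytotoxic score, 0.0625 for the hair shaft score and 0.0625 for the ALADIN hair score. Genes differing from controls at both times numbered 1122 higher and 762 lower, and a median of 70.5 and 77.5 with different controls, 3 on each side. The correlation of changes was -0.92 with the ALADIN lists, and -0.91 to -0.43 without single patients.

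Among named genes the direction and the side of the threshold stayed in 1604 of 1679 fits before treatment against control, 1669 of 1837 after against before treatment and 1573 of 1670 after treatment against control, and 0 reversed. Without single libraries or patients it stayed in 2654 of 2808, 3215 of 3744 and 2502 of 2772. For list tests it stayed in 357 of 405, 397 of 442 and 375 of 405, and for list scores in 137, 143 and 144 of 148 each. The filter of 5 FPKM ended the cytotoxic (adjusted p = 0.289) and T cell (0.241) list calls before treatment and the cytotoxic call after treatment (0.214). At this number of libraries limma recovered 46.3% of simulated changes of 0.5 in log2 after against before treatment, so changes of that size can be missed.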

Other observations

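The tests in this part were chosen after the results were seen. Libraries of the same patient correlated in their deviation from the group mean between 0.0345 and 0.409, above 0.1 in 5 of 6 patients, against a median of -0.0570 for different patients. The correlation within patients estimated by limma was 0.359.

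The immediate early gene FOS averaged 192 FPKM in controls, 65.1 before and 13.4 after treatment. The immediate early list scores ran from -0.79 to 0.82 among controls.

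The interferon gamma response list was called lower after treatment and the type I list was not, which could reflect a difference between these responses. That contrast depended on single libraries and patients. The interferon gamma call ended in 5 of the 18 fits without 1 library (adjusted p up to 0.189), and the type I list was called lower in the blocked fit without replicate 6 (adjusted p = 0.00205). The interferon gamma score fell by 0.36 more than the type I score, in 4 of 6 patients (exact sign-flip p = 0.344), so a difference between them was not shown.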
